A study of Mus musculus with 16 samples.

How the data were processed

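The series holds 16 single-cell RNA sequencing libraries of mouse liver cells sorted for EpCAM, with 10000 input cells per library per the labels. Per the labels and the file headers the authors prepared them with a droplet-based 3′ kit, aligned the reads to mm10 and made the deposited counts with Cell Ranger. The file headers give version 5.0.0 for the BALB/c libraries and 5.0.1 for the mixed-background libraries, and the submitters' notes give 5.0.0. The deposited values are counts of UMIs per gene and barcode for 32285 genes, whole numbers that the authors had already limited to barcodes called as cells. Everything from there on was computed from these counts. No table of cell types was used.

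Groups and replicate numbers were read from the sample titles, with 4 libraries each in wt, Abcb4KO, Abcb4KO_Tgr5wt and Abcb4KO_Tgr5Tg. The comparisons, gene lists, markers, rule for named genes and the alternatives were set before the data were examined, apart from those said to be chosen after. The 2 comparisons were Abcb4KO vs wt and Abcb4KO_Tgr5Tg vs Abcb4KO_Tgr5wt, each within its strain background. Nothing in the labels says that the 4 libraries of a group come from separate animals, so the p values measure the spread between these libraries, which may be technical. Nothing in the labels pairs libraries of the same replicate number, and they were fitted unpaired. The deposited names of the BALB/c libraries carry sample index wells 1 to 8, with replicates 1 and 2 of both groups in wells 1 to 4 and replicates 3 and 4 in wells 5 to 8. It is not known whether the wells mark separate preparations or sequencing runs. The mixed-background libraries carry other index numbers that are not shared evenly by the groups, so no such block was fitted there.

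Barcodes with at least 500 detected genes and under 20% mitochondrial UMIs were kept. Of 101050 barcodes 7216 lay under the gene minimum and 5028 at or over the mitochondrial limit, with some failing both, and 91608 were kept. Median UMIs per kept cell ranged by library from 2535 to 8823.5 in wt, 3273.5 to 3751 in Abcb4KO, 6494 to 9531 in Abcb4KO_Tgr5wt and 6840 to 8928 in Abcb4KO_Tgr5Tg. Doublets were scored per library with Scrublet in scanpy 1.11.5, and the highest-scoring cells were marked at a rate of 0.8% per 1000 barcodes. The 5095 marked cells took part in the clustering and were left out of all sums and shares. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes chosen over libraries gave 30 principal components. A graph of 20 neighbours was clustered with the Leiden method in igraph 0.11.9 at resolution 0.6, with seed 1 and no integration of libraries. The work ran on Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19 and matplotlib 3.10.9.

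Clusters were named by marker genes of 17 cell types, and clusters whose leading genes and markers did not settle on 1 type stayed unnamed. Names end in "-like" because they rest on transcripts alone. Of 33 clusters 20 were named into 9 classes and 13 with 10891 cells stayed unnamed and out of the gene tests.

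For each class the counts of its single cells were summed per library and tested with the edgeR quasi-likelihood test (edgeR 4.0.16, R 4.3.3, filterByExpr, TMM, robust). Gpbar1 and Abcb4 were always tested. The p values are two-sided and adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. CPM are counts scaled to a library total of 1e+06 within the class. The biological coefficient of variation in cholangiocyte-like cells was 0.0928 in Abcb4KO vs wt and 0.199 in Abcb4KO_Tgr5Tg vs Abcb4KO_Tgr5wt. Other classes were tested where at least 30 cells were present in each library. A library below that was left out only if 3 or more per group remained. Log2 changes carry the standard error of the fit and levels the SD between libraries. Intervals and floors of 3 counts cover counting error only.

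The 28 gene lists, 563 distinct genes, were written from general knowledge. They were tested with camera in limma 3.58.1 at an inter-gene correlation of 0.01, beside camera with an estimated correlation and fry, and adjusted over the lists. Lists with fewer than 3 tested members were not tested. Shares of classes and of clusters were compared by exact permutation of the 70 assignments of 8 libraries, two-sided, with 0.0286 as the smallest possible p. The share of cells with a Gpbar1 UMI was taken after thinning each cell to 2000 UMIs, and shallower cells were left out. For the opposite direction, the 8 mixed-background libraries were permuted and refitted.

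The genes named in the text follow a rule that names Gpbar1 and Abcb4, the 5 largest changes in each direction among genes past the threshold, and up to 2 members per list with the smallest adjusted p past the threshold. The largest changes required a mean of at least 10 CPM over the 8 libraries and no overlap between the groups. In other classes the 3 largest in each direction are named. Predicted genes, sex-linked genes, haemoglobin, immunoglobulin and T cell receptor genes and markers of other cell types were excluded from the largest changes. Where a list had no member past the threshold, its member with the smallest p is given as values. For 1 list the results of some members the rule names are not reported here. Genes named outside the rule are said to be chosen after their values were seen. Gene positions are those of the GENCODE vM21 annotation.

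The alternatives were RLE normalization, no low-count filter, the replicate number as a block, DESeq2 1.42.0, all 16 libraries in one fit, doublets kept, a mitochondrial limit of 10%, a minimum of 1000 genes, each cell thinned to 1000 UMIs, the same number of cells per library, a resolution of 1.2, leaving out each library, and other thinning depths. For the opposite direction they also included an adjusted p of 0.01 and leaving out the marker and dissociation lists. Chosen after seeing the data were the libraries with at least 30 cholangiocyte-like cells, the closest pairs of replicates summed, and the index wells as a block or each set of wells alone.

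The pipeline was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold in each class. In cholangiocyte-like cells it recovered 90% and 95% of them in Abcb4KO vs wt, with 31 unchanged genes among 216 calls. In Abcb4KO_Tgr5Tg vs Abcb4KO_Tgr5wt it recovered 69% and 96%, with 9 among 174. In macrophage-like cells it recovered 82% and 100% in the first comparison (12 unchanged among 194 calls) and 75% and 97% in the second (13 among 185). In endothelial-like cells these were 82% and 97% (27 among 206) and 67% and 98% (13 among 178). In the second comparison hepatocyte-like cells gave 52% and 93% (8 among 153), mesenchymal-like cells 59% and 94% (11 among 164), mesothelial-like cells 57% and 96% (10 among 163) and B cell-like cells 4% and 54% (8 among 66). Camera called a raised list and 0 of 20 unchanged lists in both comparisons, and fry called the raised list only in the second. The simulated genes were drawn independently and the raised list was made of the genes raised 2- or 4-fold. The simulation therefore cannot show how often camera falsely calls lists whose genes are correlated.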

Results

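Cells from mouse liver were sorted for EpCAM, a surface protein of epithelial cells, and profiled by droplet-based single-cell RNA sequencing of transcript 3′ ends. Each captured transcript was counted once through its unique molecular identifier (UMI). The 16 libraries formed 4 groups of 4: wt and Abcb4KO on a BALB/c background, and Abcb4KO_Tgr5wt and Abcb4KO_Tgr5Tg on a BALB/c x C57BL6/J background. Abcb4 encodes the phospholipid floppase of the hepatocyte canalicular membrane, and mice without it develop sclerosing cholangitis. Gpbar1 encodes TGR5, a bile acid receptor that raises cAMP, and Tgr5Tg denotes a Tgr5 transgene. The libraries held 3373 to 9975 barcodes each. Total UMIs per library ranged from 13091724 to 31317995 in wt, 21609689 to 32164195 in Abcb4KO, 49735830 to 79136712 in Abcb4KO_Tgr5wt and 31325362 to 85935623 in Abcb4KO_Tgr5Tg. After filtering, 86513 single cells fell into 33 clusters, of which 20 were named from marker genes. These held 27662 cholangiocyte-like, 17793 hepatocyte-like, 13947 endothelial-like, 10229 macrophage-like, 3565 mesenchymal-like, 911 B cell-like, 718 T cell-like, 598 mesothelial-like and 199 neutrophil-like cells. The other 10891 cells lay in unnamed clusters, which took 1.92 to 26.2% of the cells of a wt library, 11.0 to 42.6% in Abcb4KO, 8.26 to 21.1% in Abcb4KO_Tgr5wt and 6.64 to 13.3% in Abcb4KO_Tgr5Tg.

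The comparison of Abcb4KO with wt asked what the loss of Abcb4 changes in the cells of the bile ducts. Cholangiocyte-like cells made up 38.1% ± 42.6 of the single cells in Abcb4KO and 16.4% ± 32 in wt (mean ± SD, n = 4). The difference lay within the spread between libraries (two-sided exact permutation p = 0.2, adjusted p = 0.914 over 9 classes). It was 9.25 and 9.41 percentage points without Abcb4KO replicates 1 and 2, 34.1 and 33.8 without replicates 3 and 4 and 37.6 without wt replicate 2. Wt replicates 1 to 4 held 31, 1958, 7 and 5 such cells, and Abcb4KO replicates 1 to 4 held 5295, 4732, 30 and 86. The deposited names place replicates 1 and 2 of both groups in index wells 1 to 4 and replicates 3 and 4 in wells 5 to 8. In wells 1 to 4 the shares were 1.11% and 64.3% in wt and 75.2% and 74.8% in Abcb4KO, and in wells 5 to 8 they were 0.158% and 0.0861% in wt and 0.658% and 1.61% in Abcb4KO. Hepatocyte-like cells made up 4.12% ± 5.91 in Abcb4KO and 27.9% ± 31.7 in wt, and endothelial-like cells 24.9% ± 28.4 and 33.5% ± 22.6 (exact permutation, adjusted p = 0.914 for each). The hepatocyte-like shares leave out unnamed cluster 11, which was led by Mup17 and came closest to the hepatocyte markers. It held 10.8% ± 18.4 in Abcb4KO and 5.97% ± 11.8 in wt. Within the cholangiocyte-like class, cluster 1 held 37.5% ± 5.68 of the cells in Abcb4KO and 76.0% ± 13.7 in wt, and cluster 4 held 49.1% ± 12.3 and 8.76% ± 9.96 (exact permutation p = 0.0286, the smallest possible, adjusted p = 0.0429). The leading genes of these clusters, Ces1b for cluster 1 and Rad51b for cluster 4, are among the genes that differ between the groups, so these shares are described only. Neither share passed the test with any 1 of the 4 Abcb4KO libraries left out.

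**Figure D1:**
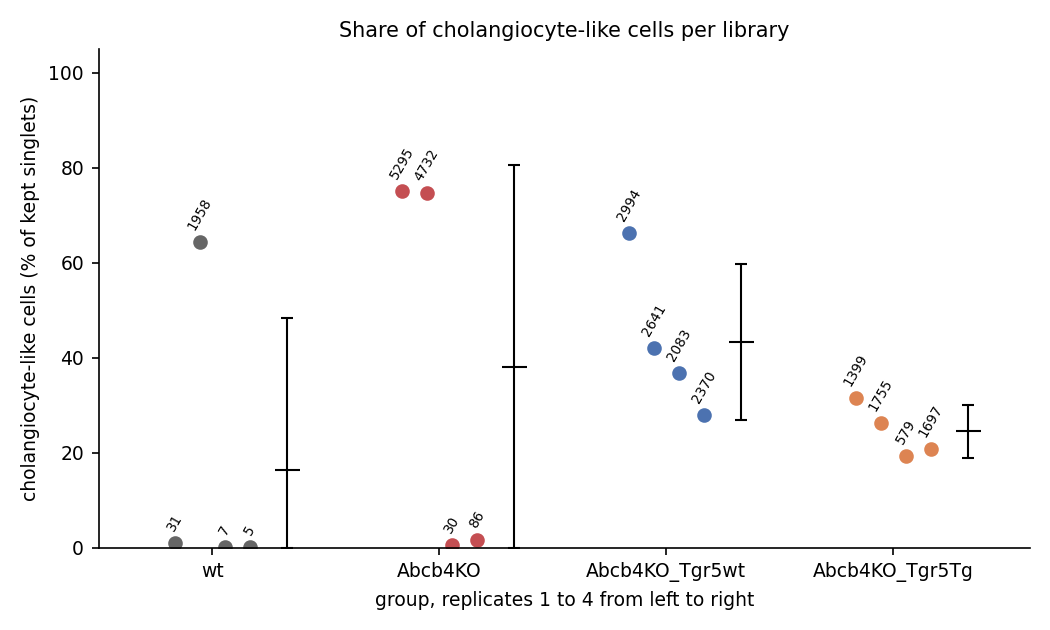
Share of cholangiocyte-like cells among single cells (%) in each library, by group, with the mean ± SD of 4 libraries as a bar and the number of cholangiocyte-like cells written at each point. Abcb4KO replicates 1 and 2 and wt replicate 2 lay between 64.3 and 75.2%, and the other 5 BALB/c libraries lay at or below 1.61%.

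In the cholangiocyte-like cells of Abcb4KO livers Ccl2 and Csf1 rose and Insig1, Cldn10 and Pigr fell. Ccl2, a chemokine that attracts monocytes, rose by 8.15 (SE 0.99) on the log2 scale, from 0.271 ± 0.542 to 280.4 ± 164 CPM (mean ± SD, n = 4, adjusted p = 0.00142). Without wt replicate 2, the one wt library with Ccl2 UMIs, the fitted change was 13.92 and was not called (adjusted p = 0.349). Csf1, the growth factor of macrophages, rose by 3.01 (SE 0.18), from 6.36 ± 7.40 to 90.2 ± 17.4 CPM (n = 4, adjusted p = 2.9e-12). Insig1, a sterol-regulated inhibitor of SREBP processing, fell by 3.58 (SE 0.13), from 142 ± 71.9 to 15.9 ± 4.57 CPM (n = 4, adjusted p = 2.0e-20). Cldn10, a claudin that forms paracellular channels, fell by 4.11 (SE 0.12), from 113 ± 27.5 to 6.23 ± 2.03 CPM (n = 4, adjusted p = 2.0e-23). Pigr, the receptor that carries IgA across epithelium into bile, fell by 3.30 (SE 0.21), from 637 ± 286 to 58.6 ± 10.7 CPM (n = 4, adjusted p = 5.0e-07).

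The remaining genes with the largest changes were Tbx1, Serpina1d, Serpina1b and Hp upward and Angptl1 and Snorc downward. Tbx1, a T-box transcription factor, rose by 6.95 (SE 0.26) to 58.2 ± 17.9 from 0.130 ± 0.259 CPM (adjusted p = 1.7e-20). Hp, which encodes haptoglobin, rose by 5.83 (SE 0.76) to 376 ± 203 from 5.66 ± 7.29 CPM (adjusted p = 0.00198). Serpina1d and Serpina1b encode paralogous alpha-1 antitrypsins, and the annotated span of Serpina1b contains that of Serpina1d, so the split of counts between them is uncertain. Serpina1d rose by 6.67 (SE 0.91) to 372 ± 197 from 22.3 ± 22 CPM (adjusted p = 0.0024), and Serpina1b rose by 6.10 (SE 0.87) to 1550 ± 709 from 97.8 ± 128 CPM (adjusted p = 0.00306). Angptl1, a secreted angiopoietin-like protein, fell by 3.77 (SE 0.22) to 4.03 ± 2.71 from 69.4 ± 23.5 CPM (adjusted p = 3.7e-15). Snorc, a transmembrane proteoglycan, fell by 2.81 (SE 0.15) to 13.5 ± 7.33 from 86.2 ± 35.7 CPM (adjusted p = 2.9e-12). Without wt replicate 2 the fitted change of Tbx1 was 11.67 (adjusted p = 0.000794), and Hp (7.29, adjusted p = 0.139), Serpina1d (4.94, 0.193) and Serpina1b (4.69, 0.083) were not called. In mm10 the 10 genes named by size of change lie on chromosome 11 at 82035571 to 82037453 (Ccl2), 16 at 18580979 to 18590671 (Tbx1), 12 at 103763594 to 103773592 (Serpina1d), 12 at 103728156 to 103830373 (Serpina1b), 8 at 109575128 to 109579172 (Hp), 14 at 118787908 to 118875489 (Cldn10), 1 at 156838562 to 156861078 (Angptl1), 5 at 28071363 to 28078662 (Insig1), 1 at 130826684 to 130852249 (Pigr) and 1 at 87470271 to 87475482 (Snorc).

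The edgeR quasi-likelihood test called 1637 of 6425 genes in cholangiocyte-like cells, 807 higher and 830 lower in Abcb4KO. The groups did not overlap for 935 genes (14.6%, against 2.86% by chance). With the index wells as a block 1985 genes were called, 1619 of them shared with the 1637 in the same direction, and 4489 and 71 genes were called in wells 1 to 4 and 5 to 8 alone. The count was 246 without wt replicate 2, 722 without Abcb4KO replicate 1, 693 without Abcb4KO replicate 2 and 842 with the closest pairs of replicates summed. It was 249 with each cell thinned to 1000 UMIs, 19 with the same number of cells from each library, 306 with DESeq2, 3200 without a low-count filter and 3519 in the libraries with at least 30 such cells.

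Abcb4 itself (ENSMUSG00000042476, chromosome 5 at 8893717 to 8959231) rose in cholangiocyte-like cells by 2.38 (SE 0.29), from 0.412 ± 0.825 to 9.51 ± 2.21 CPM (adjusted p = 1.1e-07). It was not called without wt replicate 2, the one wt library with its UMIs (8.75, adjusted p = 0.323), or without Abcb4KO replicate 1 (2.44, 0.251), 2 (2.5, 0.244) or 4 (2.59, 0.103). In libraries with at least 30 cells of a class, its mean in hepatocyte-like cells was 4.93 CPM in Abcb4KO and 17.3 in wt (n = 2 and 2). The hepatocyte-like cells of wt lay mostly in cluster 5 (5626 cells) and those of Abcb4KO mostly in cluster 7 (539, with 117 in cluster 5), so these means compare different clusters. In T cell-like cells it was 14.2 and 1.66 CPM (n = 3 and 2). A deleted gene can still give 3′ tags, so these values do not test the genotype. Gpbar1 (ENSMUSG00000064272, chromosome 1 at 74278550 to 74279624) had no UMI in the 2001 wt cholangiocyte-like cells, which allows a share of cells with a UMI of up to 0.15%, and 1 UMI in Abcb4KO. Both groups lay at the floor of 3 counts (adjusted p = 0.562), so a difference in Gpbar1 was not detectable.

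**Figure D2:**
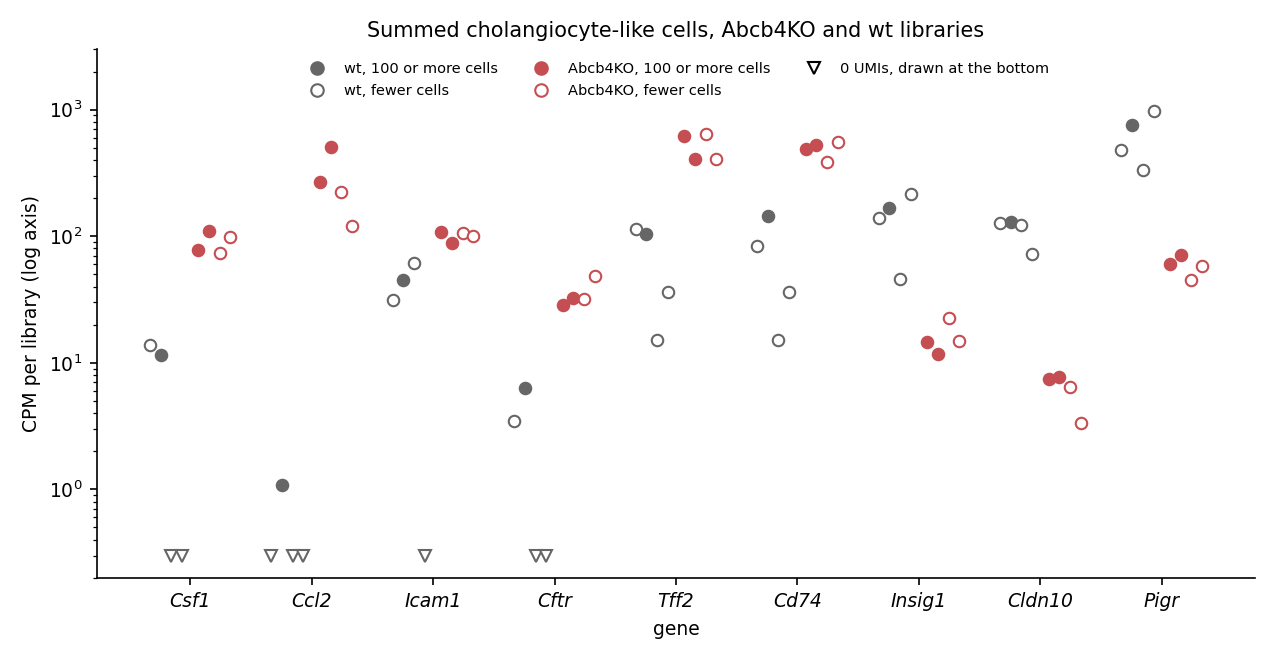
CPM of 9 genes in the cholangiocyte-like cells of each wt and Abcb4KO library, on a log axis, with filled points for libraries with at least 100 such cells, open points for fewer, and triangles at the bottom for libraries without a UMI. Csf1, Ccl2, Icam1, Cftr, Tff2 and Cd74 lay higher in the 4 Abcb4KO libraries than in the 4 wt libraries, and Insig1, Cldn10 and Pigr lay lower.

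In Abcb4KO vs wt the chemokine and inflammatory cytokine list rose as a group, with a median log2 change of 1.68 (camera adjusted p = 3.3e-05). With an estimated correlation its adjusted p was 0.347. Of 8 tested members 6 rose, over all genes and adjusted over the list alone: Ccl2, Cxcl5 and Cxcl16 are chemokines, Csf1 is a growth factor, and Icam1 and Vcam1 are adhesion molecules that bind leukocytes. Icam1 rose by 1.14 (SE 0.13), from 34.3 ± 25.9 to 100.2 ± 8.83 CPM (adjusted p = 1.3e-08). The list's median was 1.89 in index wells 1 to 4 and 3.09 in wells 5 to 8. In wells 5 to 8 the wt libraries held 7 and 5 cholangiocyte-like cells with 65522 and 27632 UMIs, so all medians there rest on few counts. The sexes differed between the groups in these wells as well. The NF-kB list, which shares Icam1, rose with a median of 0.48 (adjusted p = 0.00848, adjusted p = 0.347 with an estimated correlation), with medians of 0.79 in wells 1 to 4 and 0.58 in wells 5 to 8. It was not called in wells 5 to 8 alone (adjusted p = 0.134), and over the alternatives the adjusted p lay between 6.3e-06 and 0.861. Without wt replicate 2 its median was 0.93 (adjusted p = 0.0117). Of its 17 tested members 9 rose and Irf1 fell, with the same counts adjusted over the list alone. Tnfaip2, a TNF-induced gene, rose by 3.12 (SE 0.29), from 3.69 ± 4.92 to 38.5 ± 9.32 CPM (adjusted p = 2.3e-10), and the subunit genes Relb, Nfkb1 and Nfkb2 were among those that rose. Acute phase and antimicrobial genes rose with a median of 1.02 (adjusted p = 0.0256, adjusted p = 0.347 with an estimated correlation). Cfb, Hp, C3, Wfdc2 and Wfdc18 rose and Pigr fell among 9 tested, with the same counts adjusted over the list alone. The median was 1.05 in index wells 1 to 4 and 1.62 in wells 5 to 8. Cfb, complement factor B, rose by 1.42 (SE 0.15), from 149 ± 23.5 to 356 ± 73.0 CPM (adjusted p = 3.7e-09). Transcripts abundant in hepatocytes moved beside these lists: of 8 tested members of the hepatocyte list Apoa1, Serpina1a, Serpina1c and Fga rose and Alb fell, with the same counts adjusted over the list alone (camera adjusted p = 0.477, median 0.99). Apoa1 rose by 3.94 (SE 0.49, adjusted p = 0.00143), but by 1.46 without wt replicate 2 (adjusted p = 0.483), and Alb fell by 0.74 (SE 0.13, adjusted p = 3.1e-05).

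In Abcb4KO vs wt all 18 tested members of the cholesterol synthesis list fell, over all genes and adjusted over the list alone, with a median log2 change of −1.86 (camera adjusted p = 4.8e-16). With an estimated correlation between genes the adjusted p was 0.347, at an estimated correlation of 0.875, and fry gave 0.043. The median was −1.97 in index wells 1 to 4 and −1.88 in wells 5 to 8. For this list and the next, the wt libraries of wells 5 to 8 held only 7 and 5 cells. Most members are enzymes of the pathway, such as Sqle and Idi1. Stard4 carries sterols, Srebf2 is the transcription factor of the pathway and Insig1 restrains its processing. The cAMP and CREB list fell with a median of −0.39 (adjusted p = 0.0298, adjusted p = 0.347 with an estimated correlation). Of its 10 tested members Ppargc1a, a coactivator induced by CREB, fell by 1.23 (SE 0.15, adjusted p = 6.3e-08) and Pde3b, an enzyme that degrades cAMP, fell by 1.11 (SE 0.16, adjusted p = 2.7e-06), over all genes and adjusted over the list alone. Its median was −0.14 in index wells 1 to 4, where it was not called (adjusted p = 0.295), and −0.83 in wells 5 to 8. It was also not called without wt replicate 3 (median −0.25, adjusted p = 0.0512) or Abcb4KO replicate 1 (0.0602), 2 (0.089) or 4 (0.108), and over the alternatives the adjusted p lay between 0.00209 and 0.295. Dissociation stress genes moved beside these lists in both directions: of 23 tested 4 rose and 8 fell, and 4 and 9 adjusted over the list alone (camera adjusted p = 0.0701). Hspb1, a small heat shock protein, rose by 1.2 (SE 0.17, adjusted p = 2.0e-05) and Jund, an AP-1 subunit, fell by 0.81 (SE 0.14, adjusted p = 6.2e-05).

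Camera did not call the remaining 16 lists tested, though members of most of them changed. Fry called the 5 lists that camera called and 3 of these 16, bile acid sensing and transport downward and bicarbonate and fibrogenic genes upward (adjusted p = 0.043 for each). Among 7 bicarbonate and fluid secretion genes 3 rose, and Cftr, the chloride channel of bile duct cells, rose by 2.36 (SE 0.22), from 2.44 ± 3.05 to 35.3 ± 8.73 CPM (adjusted p = 3.1e-10). P2rx4, an ATP-gated channel, fell by 0.65 (SE 0.11, adjusted p = 1.6e-05). Of 18 fibrogenic genes 7 rose, among them Tgfb2, a TGF-beta ligand, by 1.32 (SE 0.15, adjusted p = 4.6e-08), and Itgav, an integrin subunit that activates latent TGF-beta, by 1.25 (SE 0.14, adjusted p = 8.5e-08). In the biliary identity list 1 of 18 rose and 6 fell, with Foxj1, a transcription factor of ciliated cells, higher at 123 ± 23.8 CPM in Abcb4KO and 23.3 ± 26.9 in wt (adjusted p = 2.4e-09) and Prom1, a membrane protein of progenitor cells, lower by −1.48 (SE 0.13, adjusted p = 3.8e-09). Slc10a2, the apical bile acid transporter, rose by 1.16 (SE 0.15, adjusted p = 1.2e-06) and Abcb1a, a drug efflux pump, fell by 1.76 (SE 0.11, adjusted p = 7.4e-15). Cldn8 fell by 1.55 (SE 0.22, adjusted p = 2.9e-06). Tff2, a trefoil factor of mucus, rose by 2.35 (SE 0.27), from 67.6 ± 49.3 to 520 ± 128 CPM (adjusted p = 0.000136), and Muc1, a membrane mucin, fell by 1.21 (SE 0.23, adjusted p = 0.0038). Without wt replicate 2 Cftr rose by 3.59 (adjusted p = 0.0255), and Slc10a2 (0.38, adjusted p = 0.683) and Muc1 (−1.10, 0.191) were not called.

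Cd74, the invariant chain of MHC class II, rose by 2.03 (SE 0.25), from 69.6 ± 57.1 to 491 ± 73.5 CPM (adjusted p = 0.000171), and the class II gene H2-Ab1 was at 187 ± 46.1 and 99.9 ± 37.9 CPM (adjusted p = 0.00608). In MHC class I 1 of 14 rose and 5 fell, with Cd1d1, a lipid-presenting molecule, rising by 1.45 (SE 0.13, adjusted p = 7.2e-11) and H2-Q4 falling (adjusted p = 0.00044, log2 change −0.61). The interferon list split as well, 2 of 12 up and 5 down, with Bst2 rising by 1.2 (SE 0.14, adjusted p = 2.2e-08) and Ifitm3 by 0.66 (SE 0.12, adjusted p = 0.000121). Trp53 rose by 0.88 (SE 0.13, adjusted p = 3.7e-06), and Gdf15, a stress-induced cytokine, fell by 0.94 (SE 0.20, adjusted p = 0.0006). In the unfolded protein response list 5 of 17 rose and 2 fell, with the chaperone cofactors Sdf2l1 at +1.09 (adjusted p = 8.3e-05) and Manf at 188 ± 12 and 130.2 ± 22.4 CPM (adjusted p = 0.00433). Vegfa fell by 0.83 (adjusted p = 6.5e-07), Osgin1 by 0.76 (adjusted p = 5.7e-06), Ephx1 by 0.59 (adjusted p = 0.000146), Amotl1 by 0.68 (adjusted p = 2.1e-05), Tead1 by 0.37 (adjusted p = 0.0242) and Notch2 (adjusted p = 4.9e-05) from 88.3 ± 25.6 to 60.8 ± 10.9 CPM. The respiratory chain genes Cox5a and Uqcrq rose from 272 ± 112 to 457 ± 42.8 CPM (adjusted p = 0.00902) and by 0.37 (adjusted p = 0.0209). For Pkm, a glycolytic enzyme (fit −0.62, adjusted p = 0.000303), and Egfl7, an endothelial transcript (adjusted p = 0.005), the fit and the mean CPM differed in sign, since the fit weights deep libraries more. Pkm was at 55.9 ± 13.1 CPM in Abcb4KO and 51.9 ± 38.4 in wt, and Egfl7, higher in the fit, at 64.3 ± 14 and 80.1 ± 44.9. Sparc, a mesenchymal transcript, rose by 0.65 (SE 0.20, adjusted p = 0.0293).

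In Abcb4KO vs wt several of these gene calls ended when 1 library was left out. Without wt replicate 2 H2-Ab1 was at 0.96 (adjusted p = 0.0499) and Manf at 0.79 (0.0306). Without it H2-Q4 (−0.17, adjusted p = 0.832), Trp53 (0.61, 0.153), Ephx1 (−0.63, 0.104), Amotl1 (−0.11, 0.905), Notch2 (−0.60, 0.261), Uqcrq (0.42, 0.185), Pkm (−0.34, 0.689), Egfl7 (0.066, 0.958) and Sparc (0.80, 0.0736) were not called, and Tead1 changed sign (0.10, 0.894). Without Abcb4KO replicate 1 Amotl1 (−0.54, 0.0577), Tead1 (−0.34, 0.281), Cox5a (0.49, 0.0579), Uqcrq (0.36, 0.119), Egfl7 (0.35, 0.292) and Sparc (0.61, 0.122) were not called. Without Abcb4KO replicate 2 H2-Q4 (−0.55, 0.0581), Tead1 (−0.39, 0.195), Cox5a (0.43, 0.0779), Uqcrq (0.36, 0.117), Pkm (−0.47, 0.145), Manf (0.46, 0.0766), Egfl7 (0.37, 0.295) and Sparc (0.62, 0.114) were not called. Sparc was also not called without wt replicate 1 (0.63, 0.108) or 3 (0.69, 0.0564) or Abcb4KO replicate 4 (0.63, 0.0554).

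Camera gave these lists adjusted p values of 0.94 for biliary identity, 0.393 for bile acid sensing and transport, 0.669 for bicarbonate, 0.0591 for fibrogenic genes, 0.97 for senescence, 0.574 for cell cycle, 0.222 for MHC class I, 0.703 for interferon response, 0.477 for YAP and TEAD targets, 0.777 for Notch, 0.735 for tight junction, 0.0715 for oxidative phosphorylation, 0.94 for glycolysis and hypoxia, 0.869 for the unfolded protein response, 0.97 for NRF2 and 0.213 for genes near Gpbar1. Adjusted over the list alone, members up and down numbered 4 and 7 of 18 for biliary identity, 1 and 3 of 6 for bile acids, 3 and 3 of 7 for bicarbonate, 8 and 1 of 18 for fibrogenic genes, 2 and 2 of 11 for senescence, 1 and 6 of 14 for MHC class I, 2 and 7 of 12 for interferon, 2 and 4 of 18 for tight junction, 2 and 2 of 14 for glycolysis, 5 and 3 of 17 for the unfolded protein response and 1 and 2 of 13 for NRF2. Over all genes they numbered 1 and 3 for bile acids, 3 and 2 for bicarbonate, 7 and 0 for fibrogenic genes, 2 and 2 for senescence, 1 and 4 for tight junction, 2 and 2 for glycolysis and 1 and 2 for NRF2. Of 15 tested YAP and TEAD targets 2 fell and of 4 Notch genes 1 fell, with the same counts adjusted over the list alone, while 3 of 33 oxidative phosphorylation genes rose, and 1 adjusted over the list alone. Among 7 genes near Gpbar1 only Tmbim1 was called, at 48.7 ± 20.9 CPM in Abcb4KO and 49.1 ± 28.3 in wt (log2 change −0.86, adjusted p = 7.1e-06), and it was not called without wt replicate 2 (−0.59, adjusted p = 0.489). The median, the mean and the camera direction differed in sign for bile acids (median −0.06, mean 0.0054, down), senescence (0.07, 0.05, down), glycolysis (0.0016, −0.06, down), the unfolded protein response (−0.07, 0.04, up) and NRF2 (0.10, −0.04, down). The MHC class II, mucin, immune, mesenchymal and endothelial lists had fewer than 3 tested members and were not tested as groups. Unnamed cluster 23, led by Cenpf, lay outside these sums, so the cell cycle list leaves out its cells. Doublets included, Epcam was detected in 77.0% and Mki67 in 81.4% of them. The cluster held 1.41% ± 0.667 of the single cells in Abcb4KO and 0.320% ± 0.295 in wt, which was not tested. Unnamed cluster 20, led by Dmbt1 and with Epcam in 99.3%, was also outside the sums.

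In the macrophage-like cells of Abcb4KO livers Trem2, a lipid-sensing receptor of macrophages, rose by 2.12 (SE 0.27), from 95.8 ± 26.5 to 415 ± 149 CPM (mean ± SD, n = 4, adjusted p = 0.00686). Cd163, the haemoglobin scavenger receptor of resident macrophages, was lower by −1.57 (SE 0.12), from 592 ± 110 to 195.5 ± 10.3 CPM (n = 4, adjusted p = 1.4e-07). Syngr1, a vesicle protein, rose by 2.82 (SE 0.46, adjusted p = 0.00706, not called without wt replicate 2, at 3.11 and adjusted p = 0.059, or without wt replicate 3) and Sulf2, an extracellular sulfatase, rose to 17.6 ± 3.34 from 3.33 ± 1.83 CPM (adjusted p = 0.00045). C4b, a complement component, fell by 1.53 (SE 0.22, adjusted p = 0.00205) and Gbp4, an interferon-induced guanylate-binding protein with close paralogs, fell by 1.82 (SE 0.31, adjusted p = 0.00788). Abcb4 was at 15.1 ± 4.84 and 17.7 ± 2.43 CPM (adjusted p = 0.794). The edgeR test called 173 of 8494 genes, 99 higher and 74 lower. With the index wells as a block 670 genes were called, 171 of them shared with the 173 in the same direction, and 535 and 280 in wells 1 to 4 and 5 to 8 alone. The count was 79, 69 and 86 without wt replicates 1, 3 and 4, 87 and 83 without Abcb4KO replicates 1 and 2, 407 without a low-count filter and 61 with the closest pairs summed.

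In endothelial-like cells Lrg1, a glycoprotein that acts on TGF-beta signalling in vessels, rose by 2.22 (SE 0.30), from 16.5 ± 11.3 to 71.8 ± 42.3 CPM (mean ± SD, n = 4, adjusted p = 0.0147). Tmem176a, an ion channel protein, rose by 1.48 (SE 0.14), from 86.2 ± 16.1 to 266 ± 50.9 CPM (adjusted p = 4.3e-07), and Shisa9, a transmembrane protein, by 1.68 (SE 0.22, adjusted p = 4.7e-05). Sema3d, a guidance cue, fell by 1.41 (SE 0.23, adjusted p = 0.0107), Sox11, a transcription factor, by 1.64 (SE 0.24, adjusted p = 0.000175) and Vipr1, the receptor of vasoactive intestinal peptide, by 1.2 (SE 0.27, adjusted p = 0.021). Abcb4 rose by 2.93 (SE 0.36), from 1.01 ± 0.919 to 9.05 ± 6.54 CPM (adjusted p = 2.7e-05). Lrg1 was not called without wt replicate 3 (adjusted p = 0.116) or 4 (0.0723) or Abcb4KO replicate 3 (0.118) or 4 (0.224). Vipr1 was not called without wt replicate 4 (0.141) or Abcb4KO replicate 1 (0.054) or 4 (0.609), and Sema3d without Abcb4KO replicate 4 (0.0682). The edgeR test called 164 of 11012 genes, 104 higher and 60 lower, and with the index wells as a block it called 783, including the 164 in the same direction. Wells 1 to 4 and 5 to 8 alone gave 3 and 2170, and in wells 5 to 8 the sexes differed between the groups as well. The count was 918, 67 and 102 without wt replicates 1, 3 and 4, 56 and 42 without Abcb4KO replicates 3 and 4, 14 with DESeq2, 88 with doublets kept and 62 with the closest pairs summed. The hepatocyte-, T cell-, B cell-, neutrophil-, mesenchymal- and mesothelial-like classes had too few cells in too many libraries to be tested.

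The comparison of Abcb4KO_Tgr5Tg with Abcb4KO_Tgr5wt asked what the Tgr5 transgene changes in the same cells. In cholangiocyte-like cells 2 neighbours of Gpbar1 on chromosome 1 rose. Tmbim1, a membrane protein of the BAX inhibitor motif family, rose by 1.66 (SE 0.16) on the log2 scale, from 47.8 ± 6.65 to 157 ± 36.1 CPM (mean ± SD, n = 4, adjusted p = 0.0117). Pnkd, named for a human movement disorder, rose by 1.37 (SE 0.15), from 136 ± 11.1 to 365 ± 82.1 CPM (n = 4, adjusted p = 0.0162). Icam1 was at 209 ± 23.5 CPM in Abcb4KO_Tgr5Tg and 304 ± 28.3 in Abcb4KO_Tgr5wt, without overlap between libraries, but did not pass the test over all genes (adjusted p = 0.44). Cholangiocyte-like cells made up 24.5% ± 5.52 and 43.3% ± 16.4 of single cells (exact permutation p = 0.0571, adjusted p = 0.386), with a difference of −18.8 percentage points that was −11.1 without Abcb4KO_Tgr5wt replicate 1 (adjusted p = 0.771) and −23.9 without replicate 4 (adjusted p = 0.257), and hepatocyte-like cells 34.6% ± 15.5 and 13.7% ± 12.2 (p = 0.0857, adjusted p = 0.386).

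Only 3 of 14196 genes were called by edgeR in these cells, all higher in Abcb4KO_Tgr5Tg, while 886 had an unadjusted p under 0.05. The third was Gm29358, chosen after its value was seen, at 10.2 ± 2.71 and 2.80 ± 0.212 CPM (adjusted p = 0.0162). Gm29358 (chromosome 1 at 74295603 to 74298867) and Tmbim1 (74288247 to 74305622, on the other strand) lie within the span of Pnkd (74284930 to 74353694), so the assignment of reads among them is uncertain. Aamp, which lies next to Gpbar1 (74279840 to 74284738), was at 296 ± 88.9 and 136 ± 20.2 CPM (log2 change 1.07, SE 0.20, adjusted p = 0.474), and Ctdsp1 (74391509 to 74397285) at 65.0 ± 7.84 and 38.7 ± 4.88 (adjusted p = 0.451). Arpc2, on the other side of Gpbar1 (74236084 to 74268209), was at 426 ± 10.1 and 433 ± 18.2 CPM (log2 change −0.08, SE 0.08, adjusted p = 0.872). Aamp, Ctdsp1 and Arpc2 were chosen after their values were seen. As a list, the genes near Gpbar1 rose (camera adjusted p = 6.3e-13, 0.00498 with an estimated correlation, median 0.12, mean 0.65), with 2 of 16 tested members up over all genes and 6 adjusted over the list alone: Tmbim1, Pnkd, Ctdsp1, Aamp, Gpbar1 and Catip. The list includes Gpbar1 itself, at a log2 change of 3.91 from 13 against 1 UMIs, and it was not tested without Gpbar1. The groups did not overlap for 577 genes (4.06%, against 2.86% by chance). The count of called genes was 0 without Abcb4KO_Tgr5wt replicate 2, 3 or 4 or Abcb4KO_Tgr5Tg replicate 2, 1 without Abcb4KO_Tgr5wt replicate 1, 33 with DESeq2 and 10 with all 16 libraries in one fit.

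**Figure D3:**
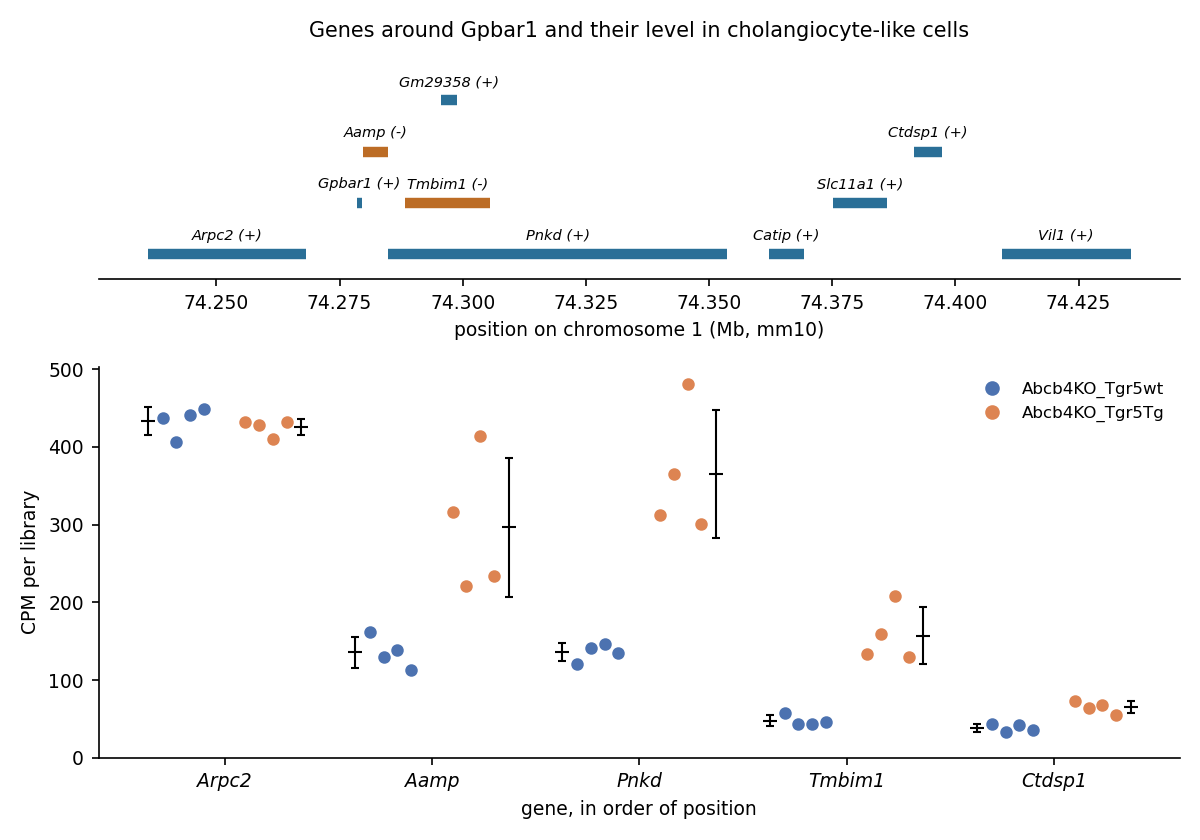
Map of mm10 chromosome 1 around Gpbar1 with genes coloured by strand, above the CPM of Arpc2, Aamp, Pnkd, Tmbim1 and Ctdsp1 in the cholangiocyte-like cells of each Abcb4KO_Tgr5wt and Abcb4KO_Tgr5Tg library, with the mean ± SD of 4 libraries. Aamp, Pnkd, Tmbim1 and Ctdsp1 lay higher in the 4 Abcb4KO_Tgr5Tg libraries, and Arpc2 was at 426 and 433 CPM.

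Gpbar1 itself was rarely captured in cholangiocyte-like cells. Over the groups 13 UMIs in Abcb4KO_Tgr5Tg stood against 1 in Abcb4KO_Tgr5wt, a ratio of 22.9 (95% counting interval 3.43 to 972). The means were 0.352 ± 0.30 and 0.00831 ± 0.0166 CPM (n = 4), and the edgeR test did not pass over all genes (adjusted p = 0.743). Abcb4KO_Tgr5Tg replicate 4 and Abcb4KO_Tgr5wt replicate 1 held 1 UMI each (0.0632 and 0.0332 CPM), under the floor of 3 counts. The share of cholangiocyte-like cells with a Gpbar1 UMI was 0.0145% ± 0.0289 and 0.00842% ± 0.0168 after thinning each cell to 2000 UMIs (exact permutation p = 1). At 4000 UMIs it was 0.156% ± 0.269 and 0.00902% ± 0.0180 (exact permutation p = 0.429), and without thinning 0.316% ± 0.268 and 0.00835% ± 0.0167 (exact permutation p = 0.0286, the smallest possible). Over all libraries 15 of 27662 cholangiocyte-like cells held a UMI (0.0542%, 95% Clopper-Pearson interval 0.0304 to 0.0894%, median 6459 UMIs per cell), against 3 of 10229 macrophage-like cells (0.0293%, median 6214) and 0 of 17793 hepatocyte-like cells (up to 0.0169%, median 5389).

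Most Gpbar1 UMIs came from mesenchymal-like cells, 859 of 890 (96.5%), where 506 of 3565 cells held one (14.2%, 95% interval 13.1 to 15.4%, median 6914 UMIs per cell). The level differed between libraries, with 31.5 CPM in wt replicate 1 against 2.88 and 4.86 (1 and 2 UMIs) in wt replicates 3 and 4. In these cells Gpbar1 was at 32 ± 6.99 CPM in Abcb4KO_Tgr5Tg and 40.6 ± 3.69 in Abcb4KO_Tgr5wt (log2 change −0.47, SE 0.17, adjusted p = 0.69). Abcb4, in cholangiocyte-like cells, was at 28.1 ± 5.86 and 22.4 ± 3.98 CPM (adjusted p = 0.814).

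**Figure D4:**
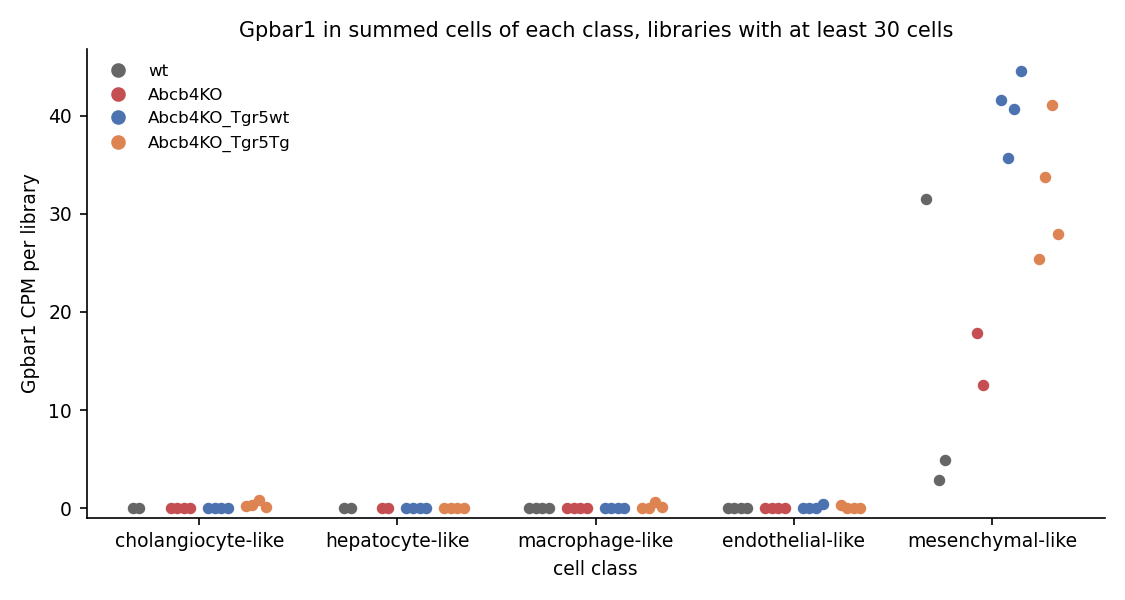
Gpbar1 CPM in each library with at least 30 cells of the class, for cholangiocyte-, hepatocyte-, macrophage-, endothelial- and mesenchymal-like cells of the 4 groups. The mesenchymal-like cells lay at means of 32 and 40.6 CPM in Abcb4KO_Tgr5Tg and Abcb4KO_Tgr5wt, and the cholangiocyte-like cells at 0.352 and 0.00831 CPM.

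In cholangiocyte-like cells the NF-kB list fell as a group in Abcb4KO_Tgr5Tg, with a median log2 change of −0.25 over 22 tested members (camera adjusted p = 2.6e-08, but adjusted p = 0.655 with an estimated correlation). Adjusted over the list alone, Icam1 and Ier3 were lower. Ier3, an early response gene, was at 792 ± 123 and 1165 ± 183 CPM (adjusted p = 0.682 over all genes). Dissociation stress genes, which share Ier3, fell beside it with a median of −0.20 over 26 members (adjusted p = 1.7e-06, adjusted p = 0.39 with an estimated correlation, 1 lower adjusted over the list alone). The chemokine and cytokine list, which shares Icam1, fell with a median of −0.14 over 21 members (adjusted p = 0.0258, 1 lower adjusted over the list alone), oxidative phosphorylation with −0.08 over 33 (adjusted p = 0.0113) and glycolysis and hypoxia with −0.11 over 23 (adjusted p = 0.0413). MHC class II rose with a median of 0.36 over 10 members, MHC class I with 0.18 over 15 and cholesterol synthesis with 0.18 over 22 (adjusted p = 0.0258 for each). For these 6 lists the adjusted p was 0.774 with an estimated correlation. For the MHC lists the members with the smallest p were Ciita, the class II transactivator, at 2.62 ± 0.482 and 1.46 ± 0.390 CPM (adjusted p = 0.765), and Nlrc5, the class I transactivator, at 7.52 ± 1.02 and 4.4 ± 1.05 (adjusted p = 0.758).

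In Abcb4KO_Tgr5Tg vs Abcb4KO_Tgr5wt several of these list calls ended when 1 library was left out. Chemokines were not called without Abcb4KO_Tgr5wt replicate 1 (adjusted p = 0.2) or 4 (0.366) or Abcb4KO_Tgr5Tg replicate 1 (0.725) or 2 (0.425). MHC class II was not called without Abcb4KO_Tgr5wt replicate 2 (0.31) or 3 (0.0682) or Abcb4KO_Tgr5Tg replicate 1 (0.145) or 4 (0.31). MHC class I was not called without Abcb4KO_Tgr5wt replicate 2 (0.154) or 4 (0.293) or Abcb4KO_Tgr5Tg replicate 1 (0.754) or 4 (0.0841). Oxidative phosphorylation was not called without Abcb4KO_Tgr5wt replicate 2 (0.198) or Abcb4KO_Tgr5Tg replicate 4 (0.0534). Glycolysis and hypoxia was not called without Abcb4KO_Tgr5wt replicate 1 (0.355) or 4 (0.052) or Abcb4KO_Tgr5Tg replicate 2 (0.0922), 3 (0.0808) or 4 (0.0841). Cholesterol synthesis was not called without Abcb4KO_Tgr5wt replicate 1 (0.0715) or Abcb4KO_Tgr5Tg replicate 1 (0.116), and its median was 0.0033 without Abcb4KO_Tgr5wt replicate 4 and −0.04 without Abcb4KO_Tgr5Tg replicate 2, where it was also not called (adjusted p = 0.929 and 0.979). The NF-kB, dissociation stress and near-Gpbar1 lists were called with each library left out. The medians moved as well. For chemokines it was −0.50 without Abcb4KO_Tgr5Tg replicate 4, −0.28 without replicate 3, −0.31 and −0.28 without Abcb4KO_Tgr5wt replicates 2 and 3 and −0.01 without replicate 4. For MHC class II it was 0.14 and 0.57 without Abcb4KO_Tgr5wt replicates 2 and 4 and 0.15 without Abcb4KO_Tgr5Tg replicate 4, and for MHC class I 0.0058 without Abcb4KO_Tgr5Tg replicate 1 and 0.11 without Abcb4KO_Tgr5wt replicate 2. For cholesterol synthesis it was 0.28 without Abcb4KO_Tgr5wt replicate 3. For oxidative phosphorylation it was −0.13 and −0.05 without Abcb4KO_Tgr5wt replicates 1 and 2 and −0.14 without Abcb4KO_Tgr5Tg replicate 2. For glycolysis and hypoxia it was −0.06 and −0.17 without Abcb4KO_Tgr5wt replicates 1 and 4 and −0.19 without Abcb4KO_Tgr5Tg replicate 1. Dissociation stress was at −0.33 without Abcb4KO_Tgr5wt replicate 4 and −0.36 without Abcb4KO_Tgr5Tg replicate 1, and the near-Gpbar1 list at 0.21 without Abcb4KO_Tgr5wt replicate 4. Fry called only the near-Gpbar1 list (adjusted p = 0.00153).

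The other lists were not called, with camera adjusted p values of 0.359 for biliary identity, 0.997 for bile acids, 0.997 for bicarbonate, 0.567 for acute phase, 0.251 for fibrogenic genes, 0.685 for senescence, 0.159 for cell cycle, 0.0905 for interferon response, 0.741 for cAMP and CREB, 0.159 for YAP and TEAD targets, 0.744 for Notch, 0.176 for mucins, 0.618 for tight junction, 0.151 for the unfolded protein response, 0.679 for NRF2, 0.0547 for hepatocyte, 0.597 for immune, 0.0994 for mesenchymal and 0.997 for endothelial transcripts. Adjusted over the list alone, Krt8 and Krt18, keratins of simple epithelium, were lower in the biliary list, with Krt8 at 2376 ± 234 and 3445 ± 399 CPM (adjusted p = 0.619 over all genes), and 1 member was lower in the cAMP list, 1 lower among the mucins and 1 higher among tight junction genes. Pigr was at 308 ± 185 and 125 ± 51.2 CPM (adjusted p = 0.798). The median, the mean and the camera direction differed in sign for bile acids (median −0.06, mean 0.17, up), bicarbonate (−0.05, −0.01, up), fibrogenic genes (0.03, −0.05, down), senescence (−0.03, 0.02, down), Notch (−0.03, 0.05, up), tight junction (−0.02, 0.10, up) and endothelial transcripts (0.02, −0.004, up).

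Aamp, Pnkd and Tmbim1 were higher in Abcb4KO_Tgr5Tg in each of the 7 cell classes tested, by 0.98 to 1.94 on the log2 scale in 20 of 20 measured combinations. In endothelial-like cells Tmbim1 rose from 110.5 ± 14.7 to 368 ± 114 CPM (adjusted p = 0.00729) and Pnkd from 115 ± 12.8 to 295 ± 82.0 (adjusted p = 0.00795). H2-Q7, a class I gene with close paralogs, was the third of 3 called genes of 10515, at 159.9 ± 17.8 and 87.5 ± 12.3 CPM (adjusted p = 0.0205). In macrophage-like cells Aamp was the 1 gene called of 10508, from 99.4 ± 9.89 to 283 ± 84.4 CPM (adjusted p = 0.0125). In mesothelial-like cells (3 against 4 libraries) Tmbim1 rose by 1.52 (SE 0.18, adjusted p = 0.000362) and Pnkd by 1.19 (SE 0.19, adjusted p = 0.0188), the 2 genes called of 7711. In hepatocyte-like cells edgeR called 0 of 10913 genes, with 686 at an unadjusted p under 0.05 and 20 called by DESeq2, and Aamp was at +1.23 (adjusted p = 0.118). In B cell-like cells (3 against 3 libraries) edgeR called 0 of 3750, with 57 at an unadjusted p under 0.05 and 0 by DESeq2. The count was 0 without Abcb4KO_Tgr5wt replicate 2, 3 or 4, 4 without Abcb4KO_Tgr5Tg replicate 2 or 3 and 54 without Abcb4KO_Tgr5Tg replicate 1 in macrophage-like cells, and 0 without Abcb4KO_Tgr5wt replicate 1 and 1 without replicate 4 in endothelial-like cells.

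In mesenchymal-like cells 26 of 11529 genes were called, 5 higher and 21 lower in Abcb4KO_Tgr5Tg. Tmbim1 rose by 1.94 (SE 0.28), Pnkd by 1.27 (SE 0.20) and Aamp by 1.00 (SE 0.17, adjusted p = 0.0373 for each), and Ifi207, an interferon-induced gene, by 1.22 (SE 0.20, adjusted p = 0.0371). Aox3, an aldehyde oxidase gene, was the fifth higher gene, and it and Aamp were chosen after their values were seen. Of the 21 lower genes 7 are biliary list or marker genes, against 0.0273 by chance. Epcam fell by 3.40 (SE 0.33), from 42 ± 10.4 to 3.16 ± 2.25 CPM (mean ± SD, n = 4, adjusted p = 0.00205), Tspan8, a tetraspanin of epithelium, from 39.7 ± 19.7 to 3.54 ± 2.06 (adjusted p = 0.0492) and Onecut2, a biliary transcription factor, from 27.5 ± 10.8 to 3.29 ± 1.18 (adjusted p = 0.0141). Krt19, at 1.69 ± 2.11 and 18.9 ± 4.84 CPM (adjusted p = 0.0388), and Clu, a secreted chaperone, at 188 ± 45 and 883 ± 266 (adjusted p = 0.0107), were chosen after their values were seen. The count was 0 with doublets kept and 56 with DESeq2. Without single libraries it was 17, 12 and 4 (Abcb4KO_Tgr5wt replicates 1 to 3) and 7, 9, 15 and 5 (Abcb4KO_Tgr5Tg replicates 1 to 4).

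Setting the comparisons side by side asked whether the transgene moved the genes that the loss of Abcb4 had moved. Of 1634 genes called in Abcb4KO against wt and tested in both, 1230 (75.3%) had the opposite sign in Abcb4KO_Tgr5Tg against Abcb4KO_Tgr5wt. Other assignments of the 8 mixed-background libraries gave shares as far from 50% often enough that the test did not pass (exact permutation p = 0.229 over 70 assignments, smallest possible 0.0286). Over 6421 genes, which are not independent replicates, the log2 changes had a Pearson correlation of −0.39 (exact permutation p = 0.343) and a Spearman correlation of −0.41 (p = 0.229). These were −0.19 and −0.19 without Abcb4KO_Tgr5Tg replicate 2, −0.24 and −0.26 without wt replicate 2 and −0.26 and −0.33 without Abcb4KO_Tgr5Tg replicate 1. Tmbim1, lower in the first comparison and higher in the second, was the 1 gene called in opposite directions, against 0.258 by chance. In the first comparison it was not called without wt replicate 2 (log2 change −0.59, adjusted p = 0.489).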

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

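The tests of explanations here were chosen only after the result was seen, except the test of the filters and the test of cholangiocyte RNA in droplets. Libraries standing apart were sought in groups of 4 by the gap between the most extreme library and its nearest neighbour, which chance marks in about 1 of 20 groups. It marked 4 of 40 groups for depth and cell shares and 24 of 205 for named genes.

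For depth and cell shares, wt replicate 2 stood apart with a median of 8823.5 UMIs per kept cell (others 2535 to 3441) and 64.3% cholangiocyte-like cells (others 0.0861 to 1.11%). Abcb4KO_Tgr5wt replicate 4 stood apart with 79136712 total UMIs, and Abcb4KO_Tgr5Tg replicate 1 with 12.6% mesenchymal-like cells (others 2.64 to 3.16%).

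For genes in cholangiocyte-like cells of wt, replicate 2 was the one library with UMIs of Abcb4 (1.65 CPM), Ccl2 (1.08 CPM) and Tbx1 (0.518 CPM). Replicates 1, 3 and 4, with 31, 7 and 5 such cells, were at 0 for these genes. Wt replicate 4 stood apart for Serpina1b at 289.5 CPM (others 17.9 to 45.8), Cldn10 at 72.4 (others 122 to 131), Abcb1a at 145 (others 90.1 to 92.4), Gdf15 at 145 (others 24.2 to 38.1) and Pde3b at 72.4 (others 27.7 to 31.7). Its 5 cells held 27632 UMIs in total, so each of these values rests on a few counts and may be counting error. Wt replicate 1 stood apart for Manf at 97 CPM (others 137 to 145). In Abcb4KO, replicate 3, with 30 cells, stood apart for Abcb4 at 12.8 CPM (others 8.24 to 8.69), Angptl1 at 0 (others 4.98 to 5.75), Prom1 at 32 (others 62.8 to 68.4), Sparc at 804 (others 1010 to 1044) and Tmbim1 at 80.1 (others 37 to 39.7). Replicate 1 stood apart for Ifitm3 at 964 CPM (others 1022 to 1028) and replicate 4 for Sdf2l1 at 39.8 (others 27.3 to 29.3).

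In the mixed background, Abcb4KO_Tgr5Tg replicate 3 stood apart for Arpc2 at 411 CPM (others 428 to 432) in cholangiocyte-like cells. In hepatocyte-like cells Abcb4KO_Tgr5Tg replicate 3 stood apart for Pnkd at 501 CPM (others 285 to 302) and Tmbim1 at 43.7 (others 16.6 to 18.5). In endothelial-like cells Abcb4KO_Tgr5wt replicate 4 stood apart for Tmbim1 at 88.5 CPM (others 116 to 119) and Abcb4KO_Tgr5Tg replicate 1 for H2-Q7 at 186 (others 149 to 152). In mesenchymal-like cells Abcb4KO_Tgr5wt replicate 2 stood apart for Tmbim1 at 49 CPM (others 69.6 to 73.7) and Abcb4KO_Tgr5Tg replicate 3 for Ifi207 at 49.3 (others 31.3 to 33.8). In macrophage-like cells wt replicate 1 stood apart for Abcb4 at 14.1 CPM (others 18.6 to 19.3).

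Abcb4 moved in opposite directions between cell classes in Abcb4KO against wt. Its mean was 9.51 and 0.825 CPM in cholangiocyte-like cells (n = 4 and 2), 14.2 and 1.66 CPM in T cell-like cells (n = 3 and 2) and 4.93 and 17.3 CPM in hepatocyte-like cells (n = 2 and 2), in libraries with at least 30 cells of the class. The hepatocyte-like cells of wt lay mostly in cluster 5 (5626 cells) and those of Abcb4KO mostly in cluster 7 (539, with 117 in cluster 5), so that class does not compare like cells. The difference between the classes was not tested.

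Some signals lay outside the comparisons. Cluster 20, unnamed and led by Dmbt1, held 3.16% of the cells of Abcb4KO_Tgr5wt replicate 4, and cluster 32, unnamed and led by the pancreatic polypeptide gene Ppy, held 1.31% of wt replicate 2. Gpbar1 was at 31.7 CPM in the mesenchymal-like cells of all libraries summed, but at 2.88 and 4.86 CPM in wt replicates 3 and 4 and at 0 in wt replicate 2 and Abcb4KO replicates 1 and 2, which held few such cells. In Abcb4KO replicate 3, 15.7% of cells had Xist and no Y-linked UMIs and 28.1% had Y-linked and no Xist UMIs, and in replicate 4 these were 15% and 28%. Each of the other 14 libraries had 1 of these signals at or below 0.427%. Abcb4KO replicates 3 and 4 therefore held cells of both sexes.

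Aamp, Pnkd and Tmbim1, which lie beside Gpbar1, were higher in the Abcb4KO_Tgr5Tg libraries in each class tested. A single mislabelled sample is argued against as the whole source, since the lowest log2 change of the 3 genes over all classes and each library left out was 0.80 (Aamp in mesothelial-like cells, where the fit of all libraries had an SE of 0.18). Extra genomic copies of the neighbouring genes carried with the transgene stay open, as the lowest log2 change over all classes, 0.98, belongs to the genes that raised the question and does not test it. Strain alleles of the linked part of chromosome 1 also stay open: the 31 other tested genes within 1 Mb, without Gm29358 inside Pnkd, had a median absolute log2 change of 0.12, but alleles can act on single genes. That median hides Catip, Slc11a1 and Ctdsp1, which lie between Pnkd and Vil1 and were chosen after their values were seen. Where tested they were at 0.62 to 1.04, 0.25 to 1.60 and 0.37 to 0.71, and none passed the threshold over all genes. Arpc2 was at −0.16 to 0.10, and Vil1 at 0.10 in cholangiocyte-like cells. An action of TGR5 on its neighbours is a biological explanation for which no test was set. In mesenchymal-like cells, with 96.5% of the Gpbar1 UMIs, Gpbar1 was at −0.47 (SE 0.17), while Aamp, Pnkd and Tmbim1 rose by 1.00, 1.27 and 1.94. For these cells this argues against an action through more counted Gpbar1 transcript in the same cells. In hepatocyte-like cells Aamp rose by 1.23 with 0 Gpbar1 UMIs in 17793 cells, which does not exclude expression. An action from other cells stays open.

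Few cholangiocyte-like cells were found in 5 of the 8 BALB/c libraries. Removal of cholangiocytes by the filters on genes, mitochondrial share or doublets is argued against, as at most 1.84% of all deposited barcodes in the 5 libraries had Epcam and a further biliary transcript, against 62.2 to 73.6% in the other 3. Of the 5 libraries 2 are Abcb4KO and the others wt, which does not test the genotype, as 5 libraries cannot fall in 1 group of 4. Within each genotype the share ranged widely, from 0.0861 to 64.3% in wt and from 0.658 to 75.2% in Abcb4KO. This spread argues against the genotype alone as the whole source. A difference between the libraries of index wells 1 to 4 and 5 to 8 stays open, as 4 of 4 libraries in wells 5 to 8 and 1 of 4 in wells 1 to 4 had few such cells, and with 5 of 8 such libraries Fisher's exact test could not have given less than p = 0.143, two-sided. The sex of the animals stays open as a biological difference that goes partly with the wells and was not tested.

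Biliary transcripts were lower in the mesenchymal-like cells of the Abcb4KO_Tgr5Tg libraries, with a median log2 change of −2.44 over the biliary identity list. Lower biliary transcripts in the cholangiocyte-like cells themselves are argued against by a median of −0.037 there. Cholangiocyte RNA in droplets of other cells stays open, as its test did not settle it: the median was −1.09 in endothelial-like, −0.80 in macrophage-like and −0.33 in hepatocyte-like cells, but −0.071 in mesothelial-like cells. In the mesothelial-like class 8 of the 19 list genes were tested. Krt19 was detected in 95.2% of the cells of its cluster, doublets included, so its median may follow its own transcripts and decides little. In B cell-like cells (3 against 3 libraries) it was 0.88 with 0 of 12 members below 0, so the change was not shared by all classes. The sort for EpCAM keeps cholangiocytes and does not remove such RNA, and an action of the transgene on mesenchymal cells was not tested.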

How the results depend on the processing

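The tests chosen only after the result was seen were those with at least 30 cholangiocyte-like cells, with the closest pairs of replicates summed, and with the index wells as a block or alone. The cause of each change given here was not tested, except that thinning, equal cell numbers, summed pairs and single sets of wells leave fewer counts or libraries by construction.

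For genes changed in cholangiocyte-like cells in Abcb4KO vs wt, against 1637, the count was 3200 without a low-count filter, 306 with DESeq2, 249 with each cell thinned to 1000 UMIs and 19 with the same number of cells per library, which left 5 cells in each. It was 3519 in libraries with at least 30 cells, 842 with pairs summed, 4489 in wells 1 to 4 alone and 71 in wells 5 to 8 alone. Leaving out single libraries gave 246 to 2294, with 246 without wt replicate 2, 722 without Abcb4KO replicate 1 and 693 without replicate 2. In all 16 libraries together 1357 genes were called, 919 higher and 438 lower, a different split from 807 and 830.

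In macrophage-like cells, against 173, the count was 407 without a filter, 61 with pairs summed, 670 with the wells as a block, 535 in wells 1 to 4 and 280 in wells 5 to 8. Leaving out single libraries gave 69 to 164, with 79, 69 and 86 without wt replicates 1, 3 and 4 and 87 and 83 without Abcb4KO replicates 1 and 2. In endothelial-like cells, against 164, it was 14 with DESeq2, 88 with doublets kept, 62 with pairs summed, 783 with the wells as a block, 3 in wells 1 to 4 and 2170 in wells 5 to 8. Leaving out single libraries gave 42 to 918, with 918, 67 and 102 without wt replicates 1, 3 and 4 and 56 and 42 without Abcb4KO replicates 3 and 4.

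For gene lists in Abcb4KO vs wt, against 5, the number called was 10 without a filter, 8 with doublets kept, 1 with thinning, 0 with equal cells, 10 in libraries with at least 30 cells, 8 with the wells as a block and 12 in wells 1 to 4 alone. Leaving out single libraries gave 4 to 11, with 11 without wt replicate 1 and 9 without Abcb4KO replicate 3. The cAMP list was not called without a filter (adjusted p = 0.212), with all 16 libraries (0.0545), a mitochondrial limit of 10% (0.0576), at least 1000 genes (0.073) or at least 30 cells (0.282), within a range of 0.00209 to 0.295. Clusters 1 and 4 of the cholangiocyte-like cells, against 2 called, gave 0 to 2 when single libraries were left out, with 0 without any 1 of the Abcb4KO libraries.

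Fitted signs reversed for Amotl1 (0.79), Tead1 (0.26), Muc1 (0.0019) and Egfl7 (−0.57) in wells 5 to 8 alone, for Tead1 without wt replicate 2 (−0.43 to 0.10 over single libraries left out) and for Abcb4 in macrophage-like cells in wells 1 to 4 alone (0.10). For all named genes of Abcb4KO vs wt, over all alternatives 1255 values kept direction and side of the threshold, 144 kept direction only and these 6 reversed, and for lists 94 and 14.

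For genes changed in cholangiocyte-like cells in Abcb4KO_Tgr5Tg vs Abcb4KO_Tgr5wt, against 3, the count was 33 with DESeq2, 10 with all 16 libraries and 0 to 3 when single libraries were left out (0 without Abcb4KO_Tgr5wt replicate 2, 3 or 4 or Abcb4KO_Tgr5Tg replicate 2, 1 without Abcb4KO_Tgr5wt replicate 1). In macrophage-like cells, against 1, it was 28 without a filter, 21 with DESeq2 and 0 to 54 without single libraries (0 without Abcb4KO_Tgr5wt replicate 2, 3 or 4, 54, 4 and 4 without Abcb4KO_Tgr5Tg replicates 1 to 3). In endothelial-like cells, against 3, it was 13, 6 and 0 to 4 (0 and 1 without Abcb4KO_Tgr5wt replicates 1 and 4). In mesenchymal-like cells, against 26, it was 46, 56 and 4 to 33, and 0 with doublets kept (17, 12 and 4 without Abcb4KO_Tgr5wt replicates 1 to 3, 7, 9, 15 and 5 without Abcb4KO_Tgr5Tg replicates 1 to 4). In mesothelial-like cells, against 2, it was 15 without a filter and 1 to 6 without single libraries (4 without Abcb4KO_Tgr5wt replicate 1, 1 without replicate 3, 6 and 1 without Abcb4KO_Tgr5Tg replicates 1 and 2). In hepatocyte-like cells, against 0, it was 6 without a filter and 20 with DESeq2. In B cell-like cells, against 0, it was 6 without a filter and 0 to 2 without single libraries (1 without Abcb4KO_Tgr5wt replicate 3, 2 without Abcb4KO_Tgr5Tg replicate 1).

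The share of cells with a Gpbar1 UMI differed by 0.308 percentage points without thinning, past the threshold. The number of lists called, against 9, was 5 with thinning and 6 to 13 when single libraries were left out. The camera direction of the cholesterol list reversed without Abcb4KO_Tgr5Tg replicate 2 (median −0.038) and without Abcb4KO_Tgr5wt replicate 4 (median 0.0033, adjusted p = 0.929), with medians of −0.038 to 0.28 over single libraries left out. For the named genes 448 values kept direction and side of the threshold, 90 kept direction only and 23 passed it newly, and for lists 133 and 27. The share of genes with opposite direction was 62.8 to 82.7% without single libraries, 76.5% at an adjusted p of 0.01 and 75.6% in libraries with at least 30 cells.

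Whether replicate numbers pair the libraries was not settled. In cholangiocyte-like cells the correlations between libraries of equal number were 0.011, 0.022, −0.019 and −0.021 in Abcb4KO vs wt and 0.25, 0.082, −0.081 and 0.47 in the second comparison. In macrophage-like cells they were 0.083, 0.24, 0.16 and 0.097 in the first and 0.19, 0.15, 0.031 and 0.15 in the second, and in endothelial-like cells −0.054, 0.044, 0.087 and 0.055 and 0.16, 0.10, 0.048 and 0.097. Over all cells summed, which also carry the mix of cell types, they were −0.51, 0.84, 0.74 and 0.46 and 0.38, 0.53, 0.20 and 0.45. With the replicate number as a block, 570 genes were called in macrophage-like and 758 in endothelial-like cells, 8 lists and 0 subclusters in Abcb4KO vs wt. In the second comparison the block gave 12 genes in macrophage-like, 8 in endothelial-like, 1 in mesothelial-like and 36 in B cell-like cells.

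Lists and subclusters were not run with DESeq2, nor subclusters at resolution 1.2. Gpbar1 had 0 UMIs in 2001 wt cholangiocyte-like cells, which leaves a share of cells with a UMI of up to 0.15% open. This limit mostly describes wt replicate 2, which held 1958 of these cells, and does not bound the share of cells that express the gene.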

Other observations

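The tests here were chosen only after the result was seen. Other splits of the same libraries were fitted in place of the real groups, 35 for 4 against 4 libraries and 10 for 3 against 3. In Abcb4KO vs wt, no other split reached the 1637 genes of cholangiocyte-like cells (1 of 35 splits as large, highest other 754) or the 173 of macrophage-like cells (1 of 35, highest other 123). A share of 1 in 35 is the smallest these splits can give, and it was not adjusted over the results tested. In cholangiocyte-like cells wt replicate 2 held 21223200 UMIs, against 27632 to 288682 in the other wt libraries. The splits cannot separate the genotype from a difference between such unequal libraries. The split with 123 was the one between index wells 1 to 4 and 5 to 8, and with the wells as a block 670 genes were called. Chance could not be excluded for the 164 genes of endothelial-like cells (4 of 35, highest other 301) or for the 5 lists (11 of 35, highest other 8). The splits ignore the index wells, and with the wells as a block more genes were called in endothelial-like cells too.

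In Abcb4KO_Tgr5Tg vs Abcb4KO_Tgr5wt, chance could not be excluded for the count of 3 genes in cholangiocyte-like cells (6 of 35, highest other 155). The split with 155 put Abcb4KO_Tgr5wt replicates 1 and 4 and Abcb4KO_Tgr5Tg replicates 3 and 4 on 1 side, and what sets these libraries apart was not tested. The splits weigh how many genes are called, not which. The list of genes near Gpbar1, set beforehand, was called with an estimated correlation (camera adjusted p = 0.00498) and by fry (adjusted p = 0.00153). Camera at the set correlation also called it with each library left out. For that list in cholangiocyte-like cells these values argue against chance. Chance could also not be excluded for the counts of 9 lists (17 of 35, highest other 14), 1 gene in macrophage-like cells (5 of 35, highest other 39), 3 genes in endothelial-like cells (2 of 35, highest other 3) or 2 genes in mesothelial-like cells (9 of 35, highest other 13). Except for H2-Q7 in endothelial-like cells, the genes called in these 3 classes were Aamp, Pnkd or Tmbim1. These were higher in 20 of 20 measured combinations with the 7 classes (log2 change 0.98 to 1.94). The counts do not weigh this, and the classes share their libraries. For the 26 genes of mesenchymal-like cells no other split gave as many (1 of 35, the smallest share possible, highest other 3). For the 0 genes of hepatocyte-like cells (35 of 35, highest other 5) and of B cell-like cells (10 of 10, highest other 94) the splits decide nothing, as every split gives at least 0. These splits were fitted without pairs, and with the replicate number as a block the counts were 12 in macrophage-like, 8 in endothelial-like, 1 in mesothelial-like and 36 in B cell-like cells, for which no splits were run.

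Sex markers varied between replicates. Wt replicates 1 and 2 and Abcb4KO replicates 1 and 2 held Y-linked UMIs (46.3, 7.92, 40.2 and 40.2% of cells with Y-linked and no Xist UMIs), and wt replicates 3 and 4 held Xist (25.1 and 23.9% with Xist and no Y-linked UMIs). Wt replicate 2, with 1958 cholangiocyte-like cells, had Y-linked UMIs at only 16.1 CPM. They were at 190, 133 and 140 CPM in wt replicate 1 and Abcb4KO replicates 1 and 2. In 2783 of the 3043 cells of wt replicate 2 neither signal was found, and the reason was not tested. In the mixed background Abcb4KO_Tgr5Tg replicate 2 held Y-linked UMIs (64.3%), and the other 7 libraries held Xist.

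The closest libraries over all cells summed were wt replicates 3 and 4, with a chi-square per degree of freedom of 6.87, and Abcb4KO replicates 1 and 2, with 12.9. Within macrophage-like cells these were 1.42 and 3.82. The values do not show whether the libraries are separate replicates, and with the closest pairs summed 842 genes were called in cholangiocyte-like cells. Cluster 9, a hepatocyte-like cluster led by Mup21, drew 95.9% of its cells from Abcb4KO_Tgr5Tg replicate 2, where it held 44.5% of the cells. Cluster 5, a hepatocyte-like cluster led by Sult2a1, came mostly from wt replicates 3 and 4, with 14, 6, 2401 and 3313 cells, doublets included, in wt replicates 1 to 4.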
